A study of Tetrahymena thermophila with 6 samples.

How the data were processed

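The data were 6 one-colour arrays hybridised with Cy3-labelled total RNA, 1 for each of 6 strains grouped by the strain named in the labels. For each array a file of probe values was deposited, holding the Cy3 intensity of each probe spot on a linear scale, extracted with NimbleScan 2.4.31 per the file headers and neither background-corrected nor normalized between arrays. A table of processed values was deposited as well. Per the submitters' processing notes these were made with RMA (robust multi-array average), whose software and version are not given in the sources used here. The deposited values proved to be intensities on a linear scale with array medians of 114 to 120. After taking log2 they correlated across features at 0.986 with the levels computed here on every array, and at 0.996 with those computed with an offset of 0. The software that ran RMA, the source of the probe sequences and the genome build behind the design are not given in the sources used here.

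The array held 384999 probes for 28064 features (24353 with 14 probes, 3165 with 13 and 546 with another number) and 4308 probes of random sequence as controls. Background was corrected with limma 3.58.1 (R 4.3.3) by the normexp method with an offset of 50. Probe values were put on a log2 scale and quantile normalized across the 6 arrays, and each feature was summarised by median polish over its probes. Files were read with the R package data.table, version 1.17.8, and plots were drawn with matplotlib 3.10.9. A feature was taken as above background on an array when its level exceeded the 99th percentile of 1000 sets of random control probes of the same size on that array. The offset compresses fold changes of dim features. Saturated probes, 21 to 315 per array, were kept. The median raw intensity of the random probes was 182 on CU428, 210.0 on HTB1, 218 on htb1-K115R, 174 on delta-UBC2, 252 on delta-BRE1 and 225 on hht2-K4Q. The number of arrays limits the precision, since each strain had 1. All arrays were scanned on 1 day, so there was no scan-day batch to test. Each strain had its own place in the scan order, so scan order and strain cannot be told apart. Both control arrays were scanned before all mutant arrays, so a difference of controls from mutants cannot be told apart from scan order either.

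With 1 array per strain, strain comparisons were described and not tested. A feature was counted as changed when its level differed at least 2-fold, it was above background on at least 1 of the 2 arrays, and at least 80% of its probes moved the same way. The standard error of a difference was taken over the feature's probes and is not a replicate error. Where the dimmer array was not above background, a fold is given as a lower bound, against the higher of the feature's own level and the lowest level above background on that array, both normalized. Strain htb1-K115R was set against HTB1, and the other mutants and HTB1 against CU428. For classes of strains, a linear model over all 6 arrays in 3 classes (H2B ubiquitylation intact, H2B ubiquitylation mutant, H3 K4Q mutant) was fitted with limma's lmFit and eBayes with a mean trend, with Benjamini-Hochberg adjustment over 24422 features and a threshold of 0.05. That fit had 3 residual degrees of freedom and a prior of 2.67. Its p-values measure the spread between strains of a class, which are not repeats of 1 strain. Similarity of strains was measured as a correlation across features, with a different control array for each strain of a pair, both ways round. Tests of the closing section on array position, neighbouring features and feature length used the probe positions in the files.

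Feature identifiers were looked up in the gene table given for the organism, which held 26996 genes, and 0 of the 28064 identifiers matched. The files do not pair the identifiers with names, so no gene name, product or position in a genome build is given, and lists of genes fixed beforehand by product name (histones, chromatin, ubiquitin conjugation, ribosomal proteins and others) and the targeted genes were not analysed here. Probe sequences were not analysed here, so probes shared between features were not checked. The features named are those with the 2 largest rises and 2 largest falls among the changed features of each strain comparison, the same among features passing each class comparison, and the features with the smallest p that did not pass where fewer than 5 passed. The parts of the rule that need a product name were not used. Other features named in the closing section were chosen after their values were seen.

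The comparisons, the naming rule and most alternatives were fixed before the data were examined. The alternatives were an offset of 0, no background correction, median scaling, the mean of probes, odd- or even-numbered probes only, the authors' deposited values, no filter on dim features, no requirement on probes, thresholds of 1.5-fold and 4-fold, the other control array or the mean of both, leaving out each strain, eBayes without the trend or robust, an adjusted p of 0.1, and hht2-K4Q counted among the controls or left out. Leaving out strains and the 4-fold threshold for the features shared by the H2B ubiquitylation mutants were added after seeing the data. The procedure was tested on simulated data for the class comparison of H2B ubiquitylation mutants with control strains, in 21214 features with noise taken from the control arrays. The changed features were drawn from those above background on all 6 real arrays. For a strain pair only the 2-fold difference was required, without the background and probe requirements. With 100 features changed by 1.5 on the log2 scale, the class test recovered 96% and the 2-fold difference 66%, and the median estimate was 1.13. With 100 changed by 3, these were 95%, 91% and 2.19. The class test called 6 unchanged features. The simulated strains varied only as the control arrays do, and every simulated mutant held the same change. Over 24422 features, the standard deviation of the real log2 difference was 0.274 between CU428 and HTB1. Between pairs of H2B ubiquitylation mutants it was 0.505 to 0.667, so the simulated recovery is not that of the class test in the real data.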

Results

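Transcript levels were measured in 6 strains of the ciliate *Tetrahymena thermophila*, with 1 oligonucleotide array for each strain. Total RNA came from cells growing at mid-logarithmic phase in a rich peptone medium. The control strains were wild-type CU428 and HTB1, the latter labelled for the gene of histone H2B. Removal of H2B ubiquitylation was approached by 3 routes. Strain htb1-K115R carried an arginine in place of a lysine of H2B, and arginine does not accept ubiquitin. Strains delta-UBC2 and delta-BRE1 were labelled as deletions of UBC2, whose name denotes a ubiquitin-conjugating enzyme, and of BRE1, named after the yeast ligase that attaches ubiquitin to H2B. Strain hht2-K4Q carried a glutamine in place of a methylatable lysine of histone H3. The array held 28064 features, each read by a set of probes, and 24422 of them were above background on at least 1 array. The share of features above background was 72.5% for CU428, 70.8% for HTB1, 74.3% for htb1-K115R, 81.4% for delta-UBC2, 75.3% for delta-BRE1 and 77.5% for hht2-K4Q. The delta-UBC2 array also had the highest ratio of median gene probe to median random probe intensity, 2.04, against 1.45 to 1.58 on the other 5. The files do not pair feature identifiers with gene names, so features are given by identifier, and the levels of HTB1, HHT2, UBC2 and BRE1 were not analysed here. Because of this, no deletion was checked against its label. No difference between strains has a replicate check, and the standard error (SE) beside each difference covers only the spread of the feature's probes within the arrays compared. The number of arrays limits the precision of every comparison.

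The comparison of HTB1 with CU428 shows how far arrays of strains without a labelled mutation differed. TETRA00S0026458 was higher in HTB1 by 7.21 on the log2 scale (SE 0.36 over 14 probes), which is 148-fold. TETRA00S0026457 was higher by 7.02 (SE 0.11), which is 130-fold. TETRA00S0000599 was lower in HTB1, with a log2 difference of −3.91 (SE 0.11), or 15.0-fold. It was also lower in all mutants, at 8.24 to 9.46 against 11.98 in CU428, so CU428 was the array that stood apart. TETRA00S0027176 was lower as well, with a log2 difference of −3.69 (SE 0.21), or 12.9-fold, and lay between 10.18 and 10.98 on the arrays other than HTB1. Across the 21151 features above background on either array, 123 were at least 2-fold higher and 84 at least 2-fold lower in HTB1, 207 in all. The standard deviation of the log2 difference was 0.29. These 207 features are the gauge against which the counts of the mutant strains are set.

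The comparison of htb1-K115R with HTB1 asks what changed when the H2B lysine was replaced. That HTB1 is the control of this strain was assumed from its label, which does not say how HTB1 was made. TETRA00S0027200 had the largest rise as measured. Its log2 level was 11.60 in htb1-K115R and 6.92 in HTB1, where it was not above background. It was therefore at least 25-fold higher (log2 difference 4.68, SE 0.25). TETRA00S0027313 was at least 12.4-fold higher (log2 difference 3.63, SE 0.45) and was likewise not above background in HTB1. Neither rise was limited to htb1-K115R. TETRA00S0027200 was at 11.50 to 12.29 in the other mutants, and TETRA00S0027313 was at 9.83 to 10.98 there. The largest falls were those of TETRA00S0026458, lower by 83.7-fold (log2 difference −6.39, SE 0.31), and TETRA00S0026457, lower by 44.2-fold (log2 difference −5.47, SE 0.13). Both of these features were also low on the CU428 array, at log2 levels of 7.74 and 8.82, so against CU428 their direction turned, with log2 differences of 0.82 and 1.55. Of the 21500 features compared, 278 were at least 2-fold higher and 194 at least 2-fold lower in htb1-K115R. The total of 472 was 2.28 times that of the control pair, and set against CU428 instead the total was 621. Features that were higher had a median log2 level of 8.30 in HTB1, and features that were lower had one of 10.45. With the authors' deposited values the total was 1071, and without background correction it was 309.

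The comparison of delta-UBC2 with CU428 asks what changed when UBC2 was deleted. TETRA00S0004623 was 263-fold higher in delta-UBC2 (log2 difference 8.04, SE 0.07), and its log2 level of 15.48 there stood against 7.44 to 9.71 on the other 5 arrays. TETRA00S0026458 was also 263-fold higher (log2 difference 8.04, SE 0.22), but it was high in HTB1 too, at a log2 level of 14.95, and the log2 difference from HTB1 was 0.83. In delta-UBC2, 1 of its 14 probes was saturated. TETRA00S0025536 fell from a log2 level of 13.41 in CU428 to 6.75, which was not above background, so it was at least 99.97-fold lower (log2 difference −6.66, SE 0.12). On the other 5 arrays this feature lay between 13.41 and 13.74. TETRA00S0012414 was 25-fold lower (log2 difference −4.64, SE 0.27). It was at 12.06 in CU428 and 12.18 in HTB1, lower in htb1-K115R (10.04) and delta-BRE1 (10.21) too, and higher in hht2-K4Q (13.30). Of 23194 features compared, 888 were at least 2-fold higher and 748 at least 2-fold lower. Their total of 1636 was 7.90 times that of the control pair, and against HTB1 it was 1361. Changes of at least 16-fold were nearly all rises, with 57 features higher and 3 lower. The control pair had 5 higher and 0 lower at that size. Features that were lower had a median log2 level of 10.46 in CU428, and the background threshold for delta-UBC2 was 6.77. Background therefore limited falls more than rises, and the same limit bears on the counts at 16-fold for delta-BRE1 and hht2-K4Q below. With median scaling in place of quantile normalization the median of all features moved to −0.15 on the log2 scale, and the split was 920 higher and 846 lower. The authors' deposited values gave a total of 3272.

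The comparison of delta-BRE1 with CU428 asks the same of BRE1. The largest rises were those of TETRA00S0026458, 164-fold (log2 difference 7.36, SE 0.33), and TETRA00S0026457, 135-fold (log2 difference 7.08, SE 0.13), but these were high in HTB1 too, and against HTB1 the log2 differences were 0.15 and 0.06. None of their probes was saturated on the HTB1 or delta-BRE1 array, but TETRA00S0026457 lay close to the top of the scanner range on both, where a difference can be compressed. TETRA00S0011554 fell by 80.9-fold (log2 difference −6.34, SE 0.08), from a log2 level of 14.13 to 7.80. It lay between 13.56 and 14.13 on all arrays other than delta-BRE1. TETRA00S0017160 was 70.9-fold lower (log2 difference −6.15, SE 0.10), with levels of 13.98 to 14.44 on the other 5 arrays. Of 22122 features compared, 965 were at least 2-fold higher and 727 at least 2-fold lower. Their total of 1692 was 8.17 times that of the control pair, and against HTB1 it was 1773. At 16-fold or more, 29 features were higher and 14 lower. The split depended on the scaling: 57.0% of the changed features were higher after quantile normalization and 46.6% (846 higher, 968 lower) after median scaling. The authors' deposited values gave a total of 3255.

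The comparison of hht2-K4Q with CU428 asks what changed when the H3 lysine was replaced. TETRA00S0009805 rose from a log2 level of 7.09 in CU428 to 15.65, which is 376-fold (log2 difference 8.55, SE 0.15). Against HTB1, where its level was 8.27, the log2 difference was 7.38, and it was also high in htb1-K115R, at 11.82. TETRA00S0024844 was at least 67.2-fold higher (log2 difference 6.23, SE 0.13), but it was high in HTB1 too, at a log2 level of 12.07, and the log2 difference from HTB1 was 0.92. TETRA00S0025643 was at least 15.1-fold lower (log2 difference −4.26, SE 0.33) and was not above background in hht2-K4Q. It was also low in delta-UBC2 and delta-BRE1, at 6.85 and 6.59, whereas it was at 10.67 in htb1-K115R. TETRA00S0019087 was 17.4-fold lower (log2 difference −4.12, SE 0.17). Of 22595 features compared, 1087 were at least 2-fold higher and 661 at least 2-fold lower. Their total of 1748 was 8.44 times that of the control pair, and against HTB1 it was 1504. Among the features that were higher, 120 were not above background in CU428, and 21 were higher by 16-fold or more against 2 lower. Here too the split depended on the scaling, with 62.2% of changed features higher after quantile normalization and 42.2% (878 higher, 1203 lower) after median scaling. The authors' deposited values gave a total of 3671, and omitting background correction gave 1128.

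**Figure D1:**
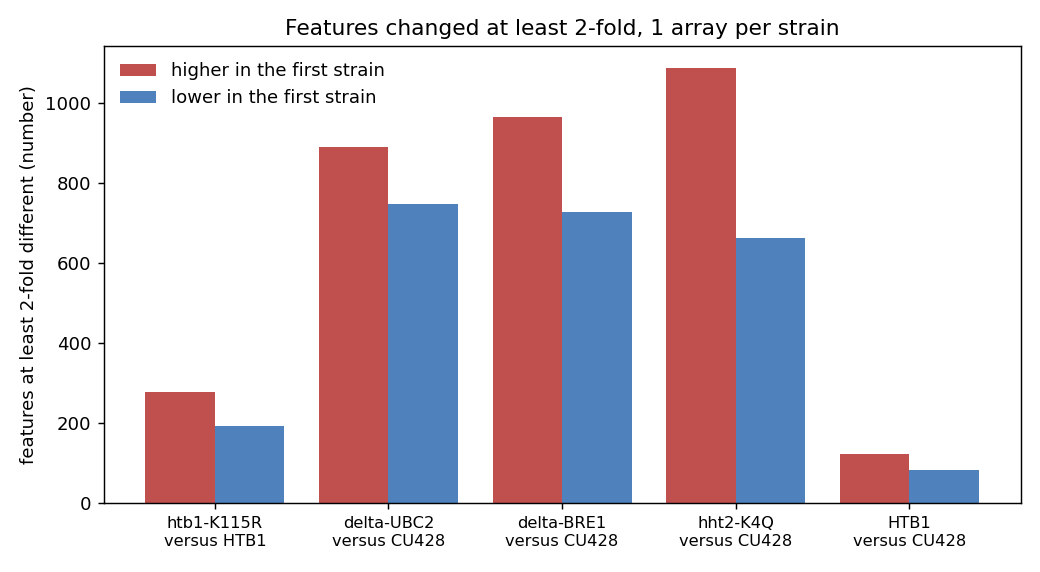
Number of features at least 2-fold higher (red) or lower (blue) in each strain comparison, with 1 array per strain and no error bars. The comparison of HTB1 with CU428 has 207 changed features, htb1-K115R has 472, and delta-UBC2, delta-BRE1 and hht2-K4Q have 1636, 1692 and 1748.

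**Figure D2:**
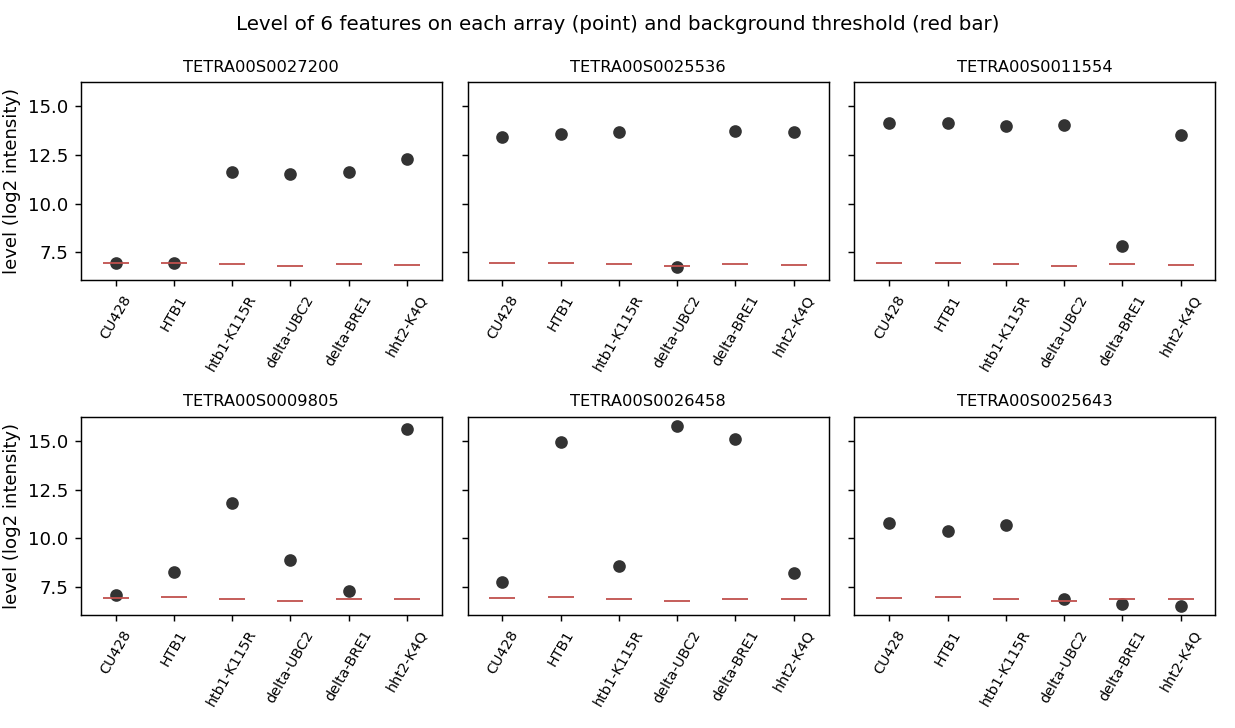
Log2 level of 6 named features on each of the 6 arrays (points), with the background threshold for sets of 14 random control probes on that array (red bars). TETRA00S0027200 is near background in CU428 and HTB1 and at 11.50 to 12.29 in the mutants, and TETRA00S0026458 is high in HTB1, delta-UBC2 and delta-BRE1.

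The class comparison asks what the H2B ubiquitylation mutants had in common against the control strains CU428 and HTB1. TETRA00S0027200 was the only feature that passed, higher in the 3 H2B ubiquitylation mutants by 4.64 on the log2 scale as measured (SE 0.15, limma adjusted p = 0.003387). Its log2 levels were 6.94 in CU428, just over the background threshold of 6.92, and 6.92 in HTB1, which was not above background. Set against these floors it was at least 25.1-fold higher in htb1-K115R, 23.5-fold in delta-UBC2 and 25.5-fold in delta-BRE1, at log2 levels of 11.60, 11.50 and 11.62. It was higher still in hht2-K4Q, at 12.29, so the rise was not limited to the H2B ubiquitylation mutants. TETRA00S0026114 was named next among the rises by its p and did not pass (log2 difference 2.67, SE 0.21, limma adjusted p = 0.2714). TETRA00S0016452 and TETRA00S0017912 were the falls named by p, not by size, and did not pass. Their log2 differences were −1.05 (SE 0.10) and −1.21 (SE 0.13), both at a limma adjusted p of 0.2783. Their levels in the H2B ubiquitylation mutants were 6.86 to 7.23, near the background thresholds of 6.77 to 6.89 on those arrays. They were also low in hht2-K4Q, at 6.81 and 7.31. Of 24422 features tested, 1 was higher and 0 were lower, while 3147 had an unadjusted p under 0.05, against 1221 expected by chance. That excess was not seen without CU428 or without HTB1, where 1 control array and 2 residual degrees of freedom were left. It was seen when any mutant array was left out. The units were strains, so the p-values measure the spread between different strains of a class, with 3 residual degrees of freedom. The call on TETRA00S0027200 was lost without CU428 (adjusted p = 0.2502), without HTB1 (0.255), without htb1-K115R (0.0918) or with hht2-K4Q counted among the controls (0.7539), all by limma, while its log2 difference stayed at 4.62 or more when any single array was left out.

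Set against both control arrays, 34 features were at least 2-fold higher and 38 at least 2-fold lower in every H2B ubiquitylation mutant. Of the 34 that were higher, 29 were also at least 2-fold higher in hht2-K4Q against both controls, where independent lists would share 1.08. Of the 38 that were lower, 18 were also lower in hht2-K4Q, where independent lists would share 0.587, and 1 was higher. In 100 simulations of unchanged strains set against the same controls, at most 1 feature was shared by 3 strains and 0 by 4. The simulated strains held no change of their own, whereas other splits of the 5 real arrays into 3 and 2 shared up to 70 features, so the simulated value is not the number that unrelated changes would give. With CU428 as the control of the H2B ubiquitylation mutants and HTB1 as that of hht2-K4Q, 56 of 92 shared rises and 26 of 72 shared falls were also seen in hht2-K4Q, where independent lists would share 3.76 and 1.49, and 7 were opposite. With the controls exchanged, these were 36 of 49 and 28 of 71, against 2.18 and 1.92 for independent lists, and 12 were opposite. The number of opposite changes for independent lists was not computed. On its own, htb1-K115R had 305 features changed in the same direction against both controls, 190 of them higher. The corresponding totals were 1101 for delta-UBC2, with 612 higher, 1315 for delta-BRE1, with 772 higher, and 1154 for hht2-K4Q, with 777 higher. Features at least 2-fold away from each of the other 5 arrays numbered 26 for htb1-K115R, 313 for delta-UBC2, 400 for delta-BRE1 and 282 for hht2-K4Q, against 34 for CU428 and 11 for HTB1. The shared total of 72 became 153 with the authors' deposited values and 5 at a 4-fold threshold. With fewer strains to satisfy, it was 287 without htb1-K115R, 153 without delta-UBC2, 122 without delta-BRE1, 120 without CU428 and 164 without HTB1.

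The hht2-K4Q strain was also set against the control strains and against the H2B ubiquitylation mutants in the same model. TETRA00S0000913 was at least 42.5-fold higher in hht2-K4Q than in the control strains, where it was not above background (log2 difference 5.64, SE 0.31, limma adjusted p = 0.01929). TETRA00S0000974 was at least 36.4-fold higher (log2 difference 5.37, SE 0.31, limma adjusted p = 0.01929). TETRA00S0019087 and TETRA00S0025731 were lower, with log2 differences of −4.01 (SE 0.28, limma adjusted p = 0.01929) and −3.06 (SE 0.30, limma adjusted p = 0.03652). In all, 59 features were higher and 8 lower, and 19 of those higher were not above background in either control strain. The split was 32 higher and 7 lower with an offset of 0, 25 and 4 with median scaling, and 25 and 8 with the deposited values. Between the H2B ubiquitylation mutants and hht2-K4Q, 53 features were higher in hht2-K4Q, led by TETRA00S0005150 with a log2 difference of −5.31 for the H2B ubiquitylation mutants minus hht2-K4Q (SE 0.31, limma adjusted p = 0.01957). The other 5 were lower in hht2-K4Q, led by TETRA00S0002674, which was not above background there and was at least 12.8-fold higher in the H2B ubiquitylation mutants (log2 difference 3.79 as measured, SE 0.40, limma adjusted p = 0.04942). With the deposited values 23 were higher and 13 lower in hht2-K4Q, with an offset of 0 these were 24 and 6, and with median scaling 18 and 2. There were 45 features that passed both tests. Both tests read the same hht2-K4Q array, so passing both is not agreement between separate measurements. The spread of the lone hht2-K4Q array was assumed from the other strains, so the fit does not separate an effect of the strain from one of its single array. That spread included the control pair, whose log2 difference had a standard deviation of 0.274. Between pairs of H2B ubiquitylation mutants it was 0.505 to 0.667, so the assumed spread may be too small for a mutant array. Both counts fell to 0 in limma without CU428, without HTB1 or without htb1-K115R, when 1815 to 4136 features had an unadjusted p under 0.05. Without delta-UBC2 the counts were 44 and 0 (2882 features at an unadjusted p under 0.05 in the latter), and without delta-BRE1 they were 184 and 102.

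The last comparison asks how alike the changes of the mutant strains were, with each member of a pair set against a different control array so that no array was shared. The correlation of log2 differences across the 24422 features was 0.287 by Pearson's r and 0.360 by Spearman's rho for delta-UBC2 and delta-BRE1, the strains labelled for loss of the conjugating enzyme and of the ligase. For delta-BRE1 and hht2-K4Q it was 0.384 by r and 0.426 by rho. Strain htb1-K115R had r of 0.363 with delta-UBC2, 0.346 with delta-BRE1 and 0.367 with hht2-K4Q, and delta-UBC2 had 0.305 with hht2-K4Q. The order of pairs depended on the measure: by r the lowest pair was delta-UBC2 with delta-BRE1 and the highest delta-BRE1 with hht2-K4Q, whereas by rho they were delta-UBC2 with hht2-K4Q (0.325) and htb1-K115R with delta-UBC2 (0.447). Changes of at least 2-fold in the same direction were shared above the number for independent lists in every pair. That number was not computed for opposite changes, which reached 171 in 1 control assignment below, against 175 features higher in both. The excess in the same direction therefore does not by itself show a change shared by the mutants. For delta-BRE1 against CU428 and hht2-K4Q against HTB1, 352 features were higher in both (39.4 for independent lists), 153 lower in both (15.1) and 55 opposite. With the controls exchanged, these were 329 (44.0), 144 (21.2) and 128. For delta-UBC2 against CU428 and delta-BRE1 against HTB1, 175 were higher in both (36.0), 179 lower in both (24.0) and 171 opposite. With the controls exchanged, these were 202 (29.6), 201 (18.2) and 80, so the number of opposite changes depended on the control array. The choice of control moved r by up to 0.164 within a pair, against a largest difference of 0.0969 between the means of pairs. Features are not independent replicates, so no p-value is given. Both control arrays were scanned before all mutant arrays, so anything the controls shared could add to every correlation and shared count.

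**Figure D3:**
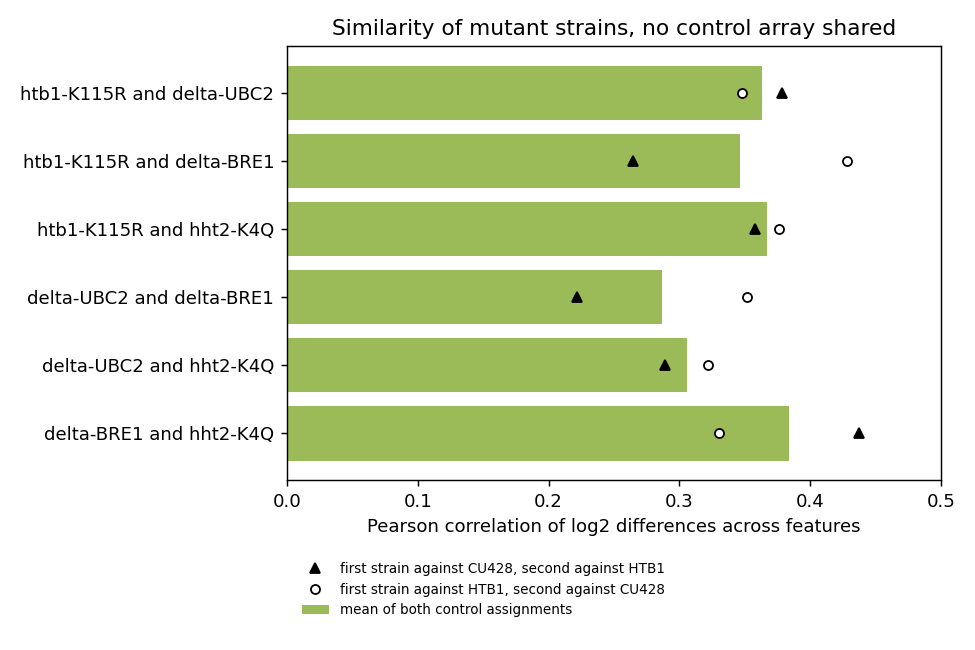
Pearson correlation across features of the log2 differences of each pair of mutant strains, with a different control array for each strain of a pair. Bars are the mean of both control assignments and symbols are the single assignments; the means lie between 0.287 and 0.384.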

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

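The comparison singled out here was fixed before the data were examined, and none of the tests in this part was chosen after the result was seen. What singled it out was a difference between the H2B ubiquitylation mutants and hht2-K4Q in their effects against the control strains: in the limma fit, 58 features passed an adjusted p of 0.05 for that difference, 53 of them higher in hht2-K4Q. TETRA00S0000913 was at a log2 level of 12.34 in hht2-K4Q and between 6.64 and 7.51 on the other 5 arrays. TETRA00S0005150 was at 14.09 in hht2-K4Q and between 8.58 and 9.12 elsewhere. In the opposite direction, TETRA00S0002674 was at 6.74 in hht2-K4Q and between 9.35 and 10.89 elsewhere. The number depended on the processing. It fell to 18 higher and 2 lower in hht2-K4Q with median scaling and to 15 and 2 without the trend in limma, and it rose to 99 and 6 without background correction. With the deposited values the split moved as well, to 23 higher and 13 lower. The hht2-K4Q side is a single array whose spread was assumed from the other strains, so an effect of the strain cannot be told apart from one of that array. Those strains include the control pair, which differed less than pairs of mutants did, so the assumed spread may be too small. Features at least 2-fold away from each of the other 5 arrays numbered 282 for hht2-K4Q, 313 for delta-UBC2 and 400 for delta-BRE1. The flagged difference therefore does not show that hht2-K4Q stood further apart than the deletion strains. The count was 0 without CU428, HTB1, htb1-K115R or delta-UBC2 and 102 without delta-BRE1.

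Other splits of the arrays were too few to give a share under 0.05. For the features changed at least 2-fold in every H2B ubiquitylation mutant against both controls, the real split of 5 arrays into 3 and 2 gave 72, the largest of 10 splits, so 1 split reached that number. The highest other split gave 70, and it set delta-UBC2 and delta-BRE1 against the remaining 3 arrays. For the class test over the same 5 arrays the real split gave 1 feature and the highest other also 1, and 3 of the 10 splits gave as many. With hht2-K4Q counted among the controls, the real split of 6 arrays into 3 and 3 gave 0 features by limma, with 1558 at an unadjusted p under 0.05. The highest other split gave 3. All 10 splits gave at least as many as the real one, which was bound to be so once the real split gave 0.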

How the results depend on the processing

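Leaving out strains and the 4-fold threshold for the shared features were chosen after seeing the data; all other alternatives were planned. Of 172 recomputed differences of named features, 108 stayed within the probe error, 62 moved and 2 changed sign. With CU428 as the control of htb1-K115R, TETRA00S0026458 was at 0.82 and TETRA00S0026457 at 1.55, because HTB1 differs from CU428 at both. Every feature counted as changed was counted in the same direction with an offset of 0. So was every one with the deposited values except in hht2-K4Q, where 1746 of 1748 were. Removing the offset widens differences, and the deposited values were used with the background calls and probe requirement computed here. Neither of these alternatives could readily lose a feature. Without background correction, 61.8% to 70.9% of the features counted as changed were kept. Counts of changed features below are in the order htb1-K115R, delta-UBC2, delta-BRE1, hht2-K4Q and HTB1. They were 1071, 3272, 3255, 3671 and 574 with the deposited values, 1572, 4690, 4542, 5041 and 710 at 1.5-fold, and 86, 305, 323, 326 and 34 at 4-fold. Without background correction htb1-K115R had 309, hht2-K4Q 1128 and HTB1 128, and with an offset of 0 HTB1 had 312. The fold threshold moves these counts by its construction. For the deposited values the cause was not tested. Other counts of changed features stayed within 1.5 times of those reported.

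In limma's class tests, the count for hht2-K4Q against the control strains was 39 with an offset of 0, 29 with median scaling, 33 with the deposited values and 194 at an adjusted p of 0.1. The count for the H2B ubiquitylation mutants against hht2-K4Q was 30, 20, 36 and 160 under these, 105 without background correction and 17 without the trend. Without 1 array at a time, the first ranged from 0 to 184 and the second from 0 to 102, with 0 for both without CU428, HTB1 or htb1-K115R. Without delta-UBC2 they were 44 and 0, and without delta-BRE1 184 and 102. Leaving out any strain but hht2-K4Q leaves 2 residual degrees of freedom. The H2B ubiquitylation mutants against the control strains gave 0 to 1 features: TETRA00S0027200 was lost without CU428, HTB1 or htb1-K115R, and with hht2-K4Q counted among the controls, where the count was 0, and passed under the other alternatives run for this test, which did not include odd- or even-numbered probes.

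The features shared by the H2B ubiquitylation mutants numbered 153 with the deposited values, 342 at 1.5-fold, 5 at 4-fold and 120 to 287 without 1 array at a time, highest without htb1-K115R. The correlation of htb1-K115R with delta-UBC2 was 0.341 with median scaling and 0.329 with the deposited values. That of htb1-K115R with hht2-K4Q was 0.340 with an offset of 0, 0.388 without background correction and 0.322 with the deposited values. That of delta-UBC2 with hht2-K4Q was 0.251 with median scaling and 0.263 with the deposited values. The cause of these shifts was not tested. Alternatives for gene lists were not run, since the files do not pair features with names. No paired analysis was possible because each strain has 1 array and the groups share only the number 1. Signal over background, a median ratio of 1.45 to 2.04 per array, limits what dim features can show.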

Other observations

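The tests of HTB1 against CU428 for TETRA00S0027200, of the shuffled order of neighbouring features, of the length relation in HTB1 and of that within the middle and bright groups were chosen after the result was seen, as were all features singled out in this part. The inner-probe test of length was added after seeing the data but before its value was seen, and both bootstrap intervals were added afterwards. A group of 3 consecutively numbered features switched between extremes across strains: TETRA00S0026457, TETRA00S0026458 and the feature numbered next. On the HTB1, delta-UBC2 and delta-BRE1 arrays their log2 levels lay between 14.95 and 15.90. On the CU428, htb1-K115R and hht2-K4Q arrays they lay between 7.74 and 10.78. The gap between the dimmest bright array and the brightest dim array was 39.1-fold, 83.7-fold and 31.4-fold. This division puts the control strains on opposite sides and follows neither class of mutation. Only 4 features had a gap of at least 16-fold with at least 2 arrays on each side, these 3 and TETRA00S0027200, which divided the controls from the mutants.

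Loss in a single strain was limited to the deletion strains at this size. TETRA00S0025536 was the 1 feature at least 16-fold lower in delta-UBC2 than on each other array, all of them above background, and it was not above background there, so its gap to the next array was at least 99.97-fold. In delta-BRE1, 7 features met the same condition, led by TETRA00S0017160 with a gap of 67.7-fold. No feature met it in the other 4 strains. Whether any of these features is a deleted gene was not analysed here, since the files do not pair identifiers with names.

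The rise of TETRA00S0027200 in all mutant arrays was checked for technical origins. A few bad or cross-hybridising probes are argued against, since 100% of its probes were at least 4-fold higher in every mutant array than in both controls. A local defect of the array surface is argued against too: the median distance between its probes was 1.09 times that of random probe pairs. The HTB1 array differed from CU428 by −0.025 on the log2 scale for this feature, but both readings were at or near background, so they show only that neither control had a level well above it. With 1 array per strain an effect of the mutations cannot be told apart from another feature of how the 4 strains were made or handled. It may therefore mark the mutations or the strains' history, and repeat arrays of independently made mutants would part these.

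Features with adjacent numbers changed together, with correlations over 21166 adjacent pairs of 0.156 for htb1-K115R, 0.162 for delta-UBC2, 0.157 for delta-BRE1, 0.153 for hht2-K4Q and 0.220 for HTB1. A chance order of features is excluded by shuffling, since 0 of 1000 shuffles reached the observed value in any comparison and the highest shuffled value was 0.0240. A local defect of the array surface is argued against by position: probes of neighbours lay 1.01 times as far apart as probes of unrelated features. Probes that read related neighbouring sequences alike stay open. Among pairs differing by over 3 in mean log2 level, the mutant correlations were 0.0585 at the lowest and 0.106 at the highest. Among pairs within 1 they were 0.233 to 0.273, so the correlation was stronger between neighbours of similar level. This explanation could not be parted from shared regulation of neighbours. A biological explanation by neighbourhood in the genome was not tested, because no position of the features was used here.

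Longer features tended to be higher in delta-UBC2 than in CU428, with a Spearman rho of 0.220 between log2 difference and the position of the last probe. Weaker signal at the ends of transcripts is argued against as the whole cause on these arrays. Probes at least 500 bases inside kept 0.848 of the correlation over all probes of the same 7750 features (95% bootstrap interval 0.802 to 0.888). Each strain had 1 array, so the bootstrap intervals here hold no variation between arrays. A relation of length with signal level is argued against for the middle and bright of 3 equal groups of features by level, where rho was 0.257 and 0.325, at least 1.17 times the pooled value (95% bootstrap interval 1.10 to 1.24), and stays open for the dimmest, where rho was 0.0400, or 0.182 of it. Array-to-array variation not tied to mutation is consistent with the values: HTB1 against CU428 had a rho of 0.121, 0.549 of that in delta-UBC2. The relation was 0.137 in htb1-K115R, 0.100 in delta-BRE1 and −0.015 in hht2-K4Q.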
